A study of Mus musculus with 29 samples.

How the data were processed

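The samples were 29 RNA-seq libraries of 6 groups, 5 libraries each except 4 in CA1 after context plus shock. The labels do not state whether the naive libraries of CA1 and ACC come from the same mice. RNA was extracted from CA1 or ACC and libraries were made with a TruSeq kit from polyadenylated RNA, per the labels' protocols. The strand used in counting is not stated. The submitters' processing notes name CASAVA 1.8.2, STAR 2.3.0e, SAMtools, DESeq2 and the mouse genome build mm10. The roles of these tools, the gene annotation and the tool behind the exon tables are not given in the sources used here.

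Per the file headers, 4 gene tables hold for each gene a base mean (a normalised count signal averaged by the authors over libraries), a log2 fold change, a p-value and an adjusted p-value. Another 4 tables hold the same measures per exonic bin, and list only bins with an adjusted p under 0.1. The lowest base mean in each gene table is about 10. The adjusted p-values the authors deposited equal a Benjamini-Hochberg adjustment over all genes listed to within 0.0022. The headers do not state the direction of a fold change. It was checked from the base means: between the 2 tables of a region the log2 ratio of base means rose with the difference in fold change, with slopes of 0.46 in CA1 and 0.51 in ACC (r = 0.97 and 0.99 across genes), so positive values are higher in trained mice. For exonic bins listed in both tables of a region, relative to their gene, the slopes were 1.14 in CA1 (70 bins) and 0.54 in ACC (2036 bins). The table for CA1 after shock is rounded to 2 decimals, has 24 gene names turned into dates (names were taken from the other tables by gene ID) and 402 fold changes of exactly 0. Exonic bin numbers were not mapped to coordinates.

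The plan named count models or limma on values per library first. The tables hold only the authors' comparisons, so the third choice of the plan was used: the deposited adjusted p, counted per direction. No count model was fitted here and library depth is unknown. A gene was called at a deposited adjusted p under 0.05. An error was implied for each log2 fold change by dividing it by the normal score of its p, which assumes a Wald test. In CA1 after shock, genes with an absolute log2 fold change under 0.05 were given the error of the context contrast times 1.08, the median ratio of the errors. Before the files were opened, 32 gene lists of 772 entries were fixed, covering activity and stress responses, cell type and region markers, ribosome, mitochondria, synapse, channels, chromatin, matrix, cholesterol synthesis and clock. Of these 31 had at least 5 measured members; the list of mitochondrially encoded genes had none. They were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed normal scores, two-sided, with an inter-gene correlation of 0.01, and adjusted over the 124 list tests. The correlation cannot be estimated without values per library; 0.05 was run as an alternative.

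Shock was compared with context as the difference of the 2 fold changes, with the root of the summed squared errors, which ignores the shared naive mice. Overlaps were set beside n1 × n2 / N and, between regions, a one-sided Fisher's exact (hypergeometric) test for an excess over that number. Correlations of context and shock were set beside 100 simulations of unchanged groups that share controls. Genes with a changed bin were compared with the share of called genes in the whole gene table and, chosen after seeing the data, at the same mean level. Rank correlations with length and GC used genes with a mean of at least 100. Transcript length and GC content came from the longest transcript of GENCODE M21, matched by gene ID for 99.1% of genes in each table; a spline fit with 5 knots on each was subtracted as an alternative chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, sklearn 1.9.0 and matplotlib 3.10.9 was used.

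The steps were tested on simulated data with the genes' own implied errors and 200 changed genes, drawn from those with a mean of at least 50. In CA1 after context, CA1 after shock, ACC after context and ACC after shock, 1.5-fold changes were recovered for 93%, 90%, 92% and 94% of the genes given them, and 2-fold changes for 97%, 98%, 100% and 100%. The simulations held 15123, 15107, 15270 and 15455 genes, and 14, 9, 7 and 9 unchanged genes were called. The noise came from the same errors that were used in calling, so the recovery follows from those errors.

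Named genes followed a rule fixed before the files were opened. In each contrast these were the 5 highest and 5 lowest fold changes among calls with a mean of at least 50, the 5 smallest p in each direction, the 4 smallest p of each list that was called or had at least 2 called members, and Fos, Arc, Egr1, Npas4, Fkbp5 and Sgk1. For exons they were the 5 smallest p and up to 6 members of the synaptic, receptor, channel and chromatin lists, and between shock and context the 5 smallest p. A gene named in one contrast may be given in the others. Some genes that the rule picks are not reported here. The other settings chosen before the files were opened were adjusted p under 0.01 and 0.1, an absolute log2 fold change of at least 0.25, a mean of at least 50, other settings of the list test, and an error without the shared naive mice. Count models, leaving out single libraries and other splits of the samples were not run, because they need values per library.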

Results

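The data were RNA-seq libraries of polyadenylated RNA from 2 brain regions of male mice aged 3 months: CA1, a field of the hippocampus needed for contextual memory, and the anterior cingulate cortex (ACC), a cortical region used in the recall of older memories. In contextual fear conditioning a mouse is placed in a new chamber and given a footshock, here of 0.7 mA, and a control group meets the chamber without the shock. The labels describe 29 libraries in 6 groups. In CA1 there were 5 libraries of naive mice, 5 of mice taken 1 h after the context alone and 4 of mice taken 1 h after context plus shock. In ACC there were 5 libraries of naive mice, 5 of mice taken 4 weeks after the context alone and 5 of mice taken 4 weeks after context plus shock. The values analysed here were the authors' deposited tables of each trained group against the naive mice of the same region, for genes and for exonic bins. They give 1 fold change and 1 p per feature and no value per library, so the sequencing depth of each library is unknown here and no SD over mice is given. The tables list 15123 genes for CA1 after context, 15115 for CA1 after shock, 15270 for ACC after context and 15455 for ACC after shock. The median error of a gene's log2 fold change, as implied by its p, was 0.0935, 0.1002, 0.0892 and 0.0702 in the same order. Positive values are higher in trained mice. Coordinates are mm10.

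The first comparison asked what exposure to a new context did in CA1 within 1 h. Immediate early genes, which neurons switch on within minutes of activity, rose together. Egr2 in the authors' deposited table (chromosome 10, 67535475 to 67542188) had a log2 fold change of 3.00 against naive mice (95% interval 2.62 to 3.38, adjusted p = 1.49e-49). Fos (chromosome 12, 85473890 to 85477273) was 4.45-fold higher (log2 2.15, interval 1.62 to 2.68) and Fosb 3.88-fold higher in the authors' deposited table. Homer1 (chromosome 13, 93303757 to 93404129), a postsynaptic scaffold with an activity-induced short form, was 1.88-fold higher in the authors' deposited table (adjusted p = 7.80e-40). Of the 32 measured immediate early genes 14 rose, 0 fell and 18 did not pass; 17 rose when adjusted over the list alone, and the list was called (cameraPR adjusted p = 3.11e-31). Arc, whose product acts at synapses, had a log2 fold change of 0.67 and Npas4 of -0.13 in the authors' deposited table, neither past the threshold (adjusted p = 0.136 and 0.675).

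Genes that follow the first wave of activity rose as well in CA1 after context: 13 of 33 delayed activity genes rose and 0 fell (15 adjusted over the list alone, adjusted p of the list = 1.24e-08). Among them Nfil3, a transcription factor, was higher by a log2 of 0.72 and Cdkn1a, a cell cycle inhibitor, by 0.59 in the authors' deposited table. Markers of endothelial cells and pericytes rose in 8 of 18 cases and fell in 1 (12 and 1 over the list alone, adjusted p of the list = 6.06e-09). The tight junction gene Cldn5 had a log2 fold change of 0.78 and the VEGF receptor genes Flt1 and Kdr had 0.53 each in the authors' deposited table. Of 20 heat shock and chaperone genes 5 rose, Hspa8 by 0.28 on the log2 scale in the authors' deposited table (8 over the list alone, list adjusted p = 0.000128). Glucocorticoid-responsive genes moved down as a list (2 of 25 rose and 8 fell, 2 and 9 over the list alone, list adjusted p = 0.00384, and 0.0574 at an inter-gene correlation of 0.05). Hif3a (chromosome 7, 17031507 to 17062427) had a log2 fold change of -1.15, Tsc22d3 -0.34 and Sgk1 -0.41, while Errfi1 had 0.32 in the authors' deposited table. Fkbp5, a standard glucocorticoid target, stood at -0.00284 in the authors' deposited table (adjusted p = 0.990). Synaptic adhesion and scaffold genes were called higher (5 of 39 rose and 1 fell, 8 and 1 over the list alone, list adjusted p = 0.0127), led by Homer1. The list's adjusted p was 0.246 with the length and GC trend removed, where its median went from 0.0731 to -0.000747, 0.169 at an inter-gene correlation of 0.05 and 0.0872 with ranks.

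In all, 1214 genes passed an adjusted p of 0.05 in CA1 after context, 698 higher and 516 lower, and 41 of them changed at least 2-fold. The smallest p among falling genes belonged to the RNA-binding protein gene Hnrpdl (log2 -0.36) and to Gpcpd1 (-0.39) in the authors' deposited table. Gm16586 (-0.67) and Gm12940 (-0.69), also among them in the authors' deposited table, lie over Hnrnpu and Sfpq, and the strand used in counting is not stated, so their values may hold reads of the overlapping genes. The largest falls among genes with a mean of at least 50, of Gm15564 (-1.68), RP23-81C12.3 (-1.40) and Lars2 (-1.19) in the authors' deposited table, had implied errors of 0.444, 0.407 and 0.391. Fold changes in this contrast followed the GC content of the transcript (Spearman rho 0.34 across genes, which are not independent replicates). With a trend on transcript length and GC removed, 560 genes passed. Of the 31 lists 25 were not called (adjusted p 0.0538 to 0.903). Among these, markers of the dentate gyrus, which adjoins CA1, had a median log2 fold change of 0.15, with 0 of 15 called (adjusted p = 0.0538, and 0.00947 with ranks). Markers of the neighbouring fields CA3 and CA2 had a median of -0.19, with 2 of 14 lower (adjusted p = 0.119). Clock genes were higher in 4 of 18 cases and lower in 7 (5 and 7 over the list alone) without a call (adjusted p = 0.134), and the list was called lower with the trend removed (adjusted p = 0.00672).

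The second comparison asked the same of CA1 1 h after context plus shock. The activity genes rose again. In the authors' deposited table Egr2 was 7.31-fold higher (log2 2.87, interval 2.44 to 3.30), Fosb 4.00-fold, Fos 4.17-fold and Homer1 2.08-fold. Dusp6, a phosphatase of ERK, had a log2 fold change of 0.69 (adjusted p = 1.06e-29) and Arc 0.81 (adjusted p = 0.0258) in the authors' deposited table. Npas4 went the other way, with a log2 fold change of -0.52 in the authors' deposited table (adjusted p = 0.0346). Of the 32 immediate early genes 15 rose and 1 fell (16 and 2 over the list alone, adjusted p = 2.35e-33), and of the 33 delayed activity genes 16 rose and 0 fell (20 over the list alone, adjusted p = 7.84e-18), Crem with 0.64 and Midn with 0.53 in the authors' deposited table.

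Clock genes moved down as a list in CA1 after shock: 4 of 18 rose and 9 fell (5 and 10 over the list alone, adjusted p = 4.09e-06). Dbp (chromosome 7, 45705088 to 45710155), an output gene of the circadian clock, had a log2 fold change of -1.10 (adjusted p = 1.10e-35) in the authors' deposited table. Gm129, also known as Ciart and a repressor in the clock, had -1.29 and Nr1d2 -0.47, while Nfil3, which binds the same sites as Dbp, had 0.84 in the authors' deposited table. Hif3a was 3.43-fold lower (log2 -1.78, adjusted p = 1.38e-33) in the authors' deposited table. Glucocorticoid-responsive genes moved down as a list, with 3 of 25 higher and 5 lower (3 and 9 over the list alone, list adjusted p = 0.00038). Endothelial markers rose in 7 of 18 cases (10 over the list alone with 1 lower, adjusted p = 4.29e-11), Cldn5 by 0.88 and Pecam1 by 0.56 in the authors' deposited table. Chaperones rose in 6 of 20 cases (10 over the list alone, adjusted p = 1.83e-09). Enzymes of cholesterol synthesis rose in 5 of 21 cases (5 over the list alone, adjusted p = 0.000545), among them Cyp51 with 0.34 in the authors' deposited table. Single ion channel and receptor genes rose, with Kcnj6 at 0.67, Kcnq3 at 0.66 and the AMPA receptor gene Gria1 at 0.33 in the authors' deposited table, but the potassium channel list (5 of 29 higher, adjusted p = 0.225) and the glutamate receptor list (3 of 24 higher, adjusted p = 0.724) were not called.

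After shock 915 genes passed in CA1, 485 higher and 430 lower. The balance of direction turned to 389 higher and 432 lower with the length and GC trend removed, and to 372 and 377 with an absolute log2 of at least 0.25. The lists of synaptic adhesion genes (4 of 39 higher and 1 lower, adjusted p = 0.0265) and oxidative phosphorylation genes (2 of 74 higher, adjusted p = 0.0426) were called higher but were not past the threshold with the length and GC trend removed (adjusted p = 0.106 and 0.246), at an inter-gene correlation of 0.05 (0.203 and 0.314) or among genes with a mean of at least 50 (0.0515 and 0.0880). With ranks the adjusted p of the synaptic adhesion list was 0.108. The other 22 lists were not called (adjusted p 0.119 to 0.975). In this table values were rounded to 2 decimals, and 3650 genes had an absolute log2 fold change under 0.05.

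**Figure D1:**
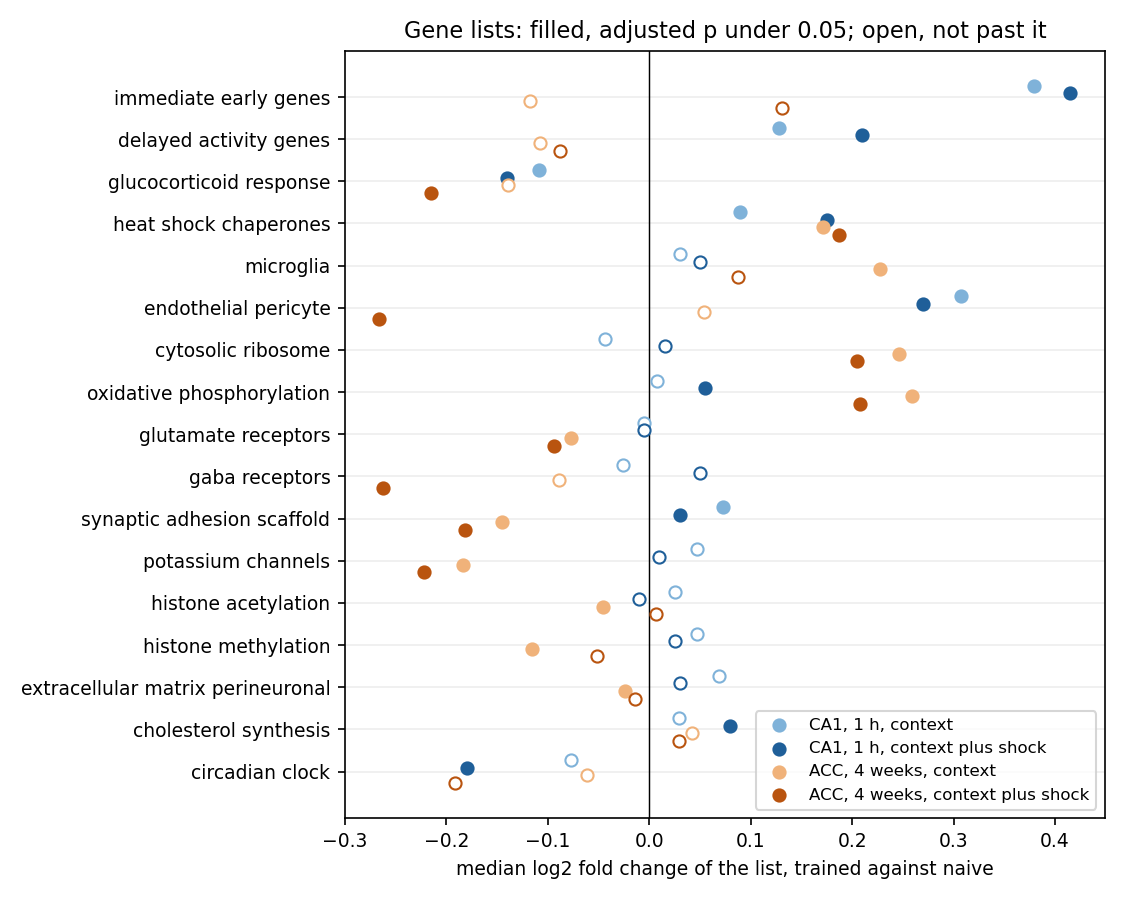
Median log2 fold change (x axis, trained against naive) of each gene list called in at least 1 contrast (y axis). Filled points are lists with an adjusted p under 0.05 in that contrast and open points are lists not past it. Immediate early genes sit at 0.38 and 0.42 in CA1, and oxidative phosphorylation genes at 0.26 and 0.21 in ACC.

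The third comparison asked how ACC differed from that of naive mice 4 weeks after a context exposure. The labels give no ACC group at an earlier time. They give 3 months as the age of every group and no age at sacrifice for the naive ACC mice. Age and the 4 weeks of waiting thus cannot be told apart from training, here and after context plus shock. Fold changes fell with transcript length in this contrast (Spearman rho -0.61 across genes, which are not independent replicates). Bin E001 of genes on the minus strand, their 3' end if bins are numbered by position, was higher in 702 of 706 called cases. Genes of the respiratory chain and of the ribosome were higher. Of 74 oxidative phosphorylation genes 51 rose and 0 fell (62 over the list alone, adjusted p = 3.88e-26), with a median log2 fold change of 0.26, and 0.0451 with the length and GC trend removed (adjusted p = 0.000342). The ATP synthase subunit gene Atp5j2 had 0.62 (adjusted p = 8.01e-19) and Cox7a2 0.42 in the authors' deposited table. Of 77 cytosolic ribosomal protein genes 37 rose and 1 fell (38 and 1 over the list alone, adjusted p = 3.22e-13), Rps14 with 0.60 and Rpl37a with 0.63 in the authors' deposited table. Their median went from 0.25 to 0.0359 with the trend removed (adjusted p = 0.0098). Potassium channel genes were lower: 16 of 29 fell and 1 rose (18 and 1 over the list alone, adjusted p = 5.30e-14), with a median of -0.18, and -0.0969 with the trend removed (adjusted p = 9.08e-08). Kcna2 in the authors' deposited table (chromosome 3, 107101567 to 107106879), a channel of axons, was 3.27-fold lower (log2 -1.71, interval -1.92 to -1.50, adjusted p = 5.26e-55). The calcium-activated channel gene Kcnma1 had a log2 fold change of -1.07 and the M-current gene Kcnq3 -1.06 in the authors' deposited table. Among 39 synaptic adhesion and scaffold genes 20 fell and 1 rose (21 and 1 over the list alone, adjusted p = 8.51e-08), Dlgap2 with -0.47 in the authors' deposited table. This list was not called with the trend removed (adjusted p = 0.126), where its median went from -0.14 to -0.0399. The glutamate receptor list was called lower with 3 of 24 genes fallen (adjusted p = 0.00908). It was not past the threshold at an inter-gene correlation of 0.05 (adjusted p = 0.0884), with ranks (0.0565) or with the length and GC trend removed (0.734), where its median went from -0.0774 to 0.0104. The genes that fell were the NMDA receptor genes Grin2b (-1.61) and Grin2a (-1.05) and the kainate receptor gene Grik3 (-0.21) in the authors' deposited table.

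Several smaller shifts were called in ACC after context. Microglial markers rose in 8 of 15 cases (12 over the list alone, adjusted p = 9.73e-06), Aif1 with 0.59 and C1qb with 0.37 in the authors' deposited table. With the length and GC trend removed the microglial median went from 0.23 to 0.14 (adjusted p = 0.00185), Aif1 to 0.34 and C1qb to 0.15, no longer past the threshold (adjusted p = 0.370). Chaperones rose in 7 of 20 cases (7 over the list alone, adjusted p = 0.00119), and their median went from 0.17 to 0.10 with the trend removed (adjusted p = 0.0327). Histone methylation genes fell in 12 of 34 cases and rose in 1 (13 and 1 over the list alone, adjusted p = 0.000104), and the list was not called with the trend removed (adjusted p = 0.709), where its median went from -0.12 to -0.048. Histone acetylation genes fell in 6 of 25 cases and rose in 1 (6 and 1 over the list alone, adjusted p = 0.0265), with Hdac4 at -0.63 and Crebbp at -0.53 in the authors' deposited table. That call was lost at an inter-gene correlation of 0.05 (adjusted p = 0.171), with ranks (0.300) and with the trend removed (0.211). Extracellular matrix and perineuronal net genes fell in 5 of 22 cases and rose in 1 (5 and 2 over the list alone, adjusted p = 0.0408), Tnr with -0.98 in the authors' deposited table. This call too was lost at an inter-gene correlation of 0.05 (adjusted p = 0.189), with ranks (0.367) and with the trend removed (0.578), where the median went from -0.024 to 0.0715. Immediate early genes were not called as a list (2 of 32 higher, adjusted p = 0.899). Fosb was higher with a log2 fold change of 0.58 (adjusted p = 0.00172), and Fos, at -0.20, was not past the threshold (adjusted p = 0.787) in the authors' deposited table. The smallest p belonged to Wdfy1 (chromosome 1, 79702262 to 79776143), 3.33-fold higher (adjusted p = 3.49e-143) in the authors' deposited table. Cd59a, a complement inhibitor, had a log2 fold change of 1.48, and Nnt, a mitochondrial transhydrogenase that differs between mouse substrains, had 0.91 in the authors' deposited table. Markers of striatum, septum and thalamus, which lie near ACC dissections, were not called as a list (5 of 17 higher and 2 lower, adjusted p = 0.458); Adora2a had 1.03, Ppp1r1b 0.50, Slc17a6 -0.40 and Rora -0.42 in the authors' deposited table.

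In ACC after context 2987 genes passed, 1431 higher and 1556 lower. The median log2 fold change was 0.15 in the shortest of 5 equal groups of genes and -0.15 in the longest, and 1356 genes passed with the length and GC trend removed. Other lists were called only under another setting: glucocorticoid-responsive genes lower with the trend removed (adjusted p from 0.267 to 0.0378), meninges markers higher with ranks (from 0.0740 to 0.0164) and DNA methylation genes lower among genes with a mean of at least 50 (from 0.0607 to 0.0468).

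The fourth comparison asked how ACC differed from that of naive mice 4 weeks after context plus shock. It held the most calls: 6433 genes passed, 3058 higher and 3375 lower, or 41.6% of those listed, with a median absolute log2 fold change of 0.25. Fold changes fell with transcript length (rho -0.53) and rose with GC content (rho 0.56), and bin E001 on the minus strand was higher in 417 of 426 called cases. Potassium channel genes fell in 19 of 29 cases and rose in 1 (19 and 1 over the list alone, adjusted p = 3.87e-13), and their median went from -0.22 to -0.14 with the length and GC trend removed (adjusted p = 3.09e-12). In the authors' deposited table Kcnma1 (chromosome 14, 23289431 to 23803304) had a log2 fold change of -1.14 (interval -1.25 to -1.03, adjusted p = 2.77e-90), Kcna2 -1.64 and Kcnh7 -0.63. Receptors of GABA fell in 11 of 14 cases and rose in 1 (11 and 1 over the list alone, adjusted p = 2.35e-06), Gabrb2 with -0.80 in the authors' deposited table, and their median went from -0.26 to -0.0945 with the trend removed (adjusted p = 0.00138). Synaptic adhesion genes fell in 25 of 39 cases and rose in 1 (25 and 1 over the list alone, adjusted p = 8.46e-10), Dlg2 with -0.59 in the authors' deposited table, and their median went from -0.18 to -0.0572 with the trend removed (adjusted p = 0.00132). Glutamate receptor genes fell in 11 of 24 cases and rose in 1 (11 and 1 over the list alone, adjusted p = 0.0265), Gria2 with -0.45 in the authors' deposited table. That call was lost at an inter-gene correlation of 0.05 (adjusted p = 0.169), with ranks (0.0805), among genes with a mean of at least 50 (0.0524) and with the trend removed (0.853), where the median went from -0.0939 to -0.0342. Oxidative phosphorylation genes rose in 51 of 74 cases and fell in 2 (56 and 2 over the list alone, adjusted p = 4.00e-14), and ribosomal protein genes rose in 40 of 79 and fell in 2 (42 and 2 over the list alone, adjusted p = 2.35e-08), Rps21 with 0.64 in the authors' deposited table. Their medians went from 0.21 to 0.0422 and from 0.20 to 0.0344 with the trend removed (adjusted p = 0.0233 and 0.0302).

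Endothelial and pericyte markers, which rose in CA1, were lower in ACC after shock: 10 of 18 fell and 2 rose (11 and 2 over the list alone, adjusted p = 0.000771), with a median of -0.27 before and after the trend was removed (adjusted p = 7.52e-08). In the authors' deposited table the transporter genes of the blood-brain barrier Abcb1a and Slco1a4 had log2 fold changes of -0.79 and -0.78, Flt1 -0.49 and Rgs5 -0.49, while Cldn5 had 0.64. Glucocorticoid-responsive genes fell in 12 of 25 cases and rose in 0 (13 over the list alone, adjusted p = 0.00453, and 0.0623 at an inter-gene correlation of 0.05). Their median went from -0.22 to -0.38 with the trend removed (adjusted p = 4.11e-08). Tsc22d3 had -0.56, Fkbp5 -0.46 (adjusted p = 3.45e-07) and Sgk1 -0.72 in the authors' deposited table. Chaperones rose in 9 of 20 cases and fell in 1 (10 and 1 over the list alone, adjusted p = 0.0378, and 0.174 at an inter-gene correlation of 0.05 and 0.0539 among genes with a mean of at least 50). Their median went from 0.19 to 0.0822 with the trend removed (adjusted p = 0.0190). Clock genes were not called (2 of 18 higher and 9 lower, 3 and 11 over the list alone, adjusted p = 0.0520), and with the length and GC trend removed the list was called lower (adjusted p = 0.0190). Nr1d2 had -0.47 and Gm129 -0.73 in the authors' deposited table. Immediate early genes were not called (3 of 32 higher and 1 lower, adjusted p = 0.385), with Jun at 0.39, Fosb at 0.62 and Egr2 at 0.90 in the authors' deposited table. Arc, Egr1 and Npas4 had 0.20, 0.16 and 0.52 in the authors' deposited table, none past the threshold. Markers of the meninges rose in 6 of 15 cases without a call (adjusted p = 0.103), Slc6a13 with 0.77 and Col1a1 with 0.44, and the choroid plexus gene Ttr had -1.30 in the authors' deposited table.

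A fit on transcript length and GC took up 49.6% of the weighted variance of fold changes in ACC after shock, and with it removed 3668 genes passed. At an inter-gene correlation of 0.05 in place of 0.01, 24 of the 34 list calls over the 4 contrasts held.

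**Figure D2:**
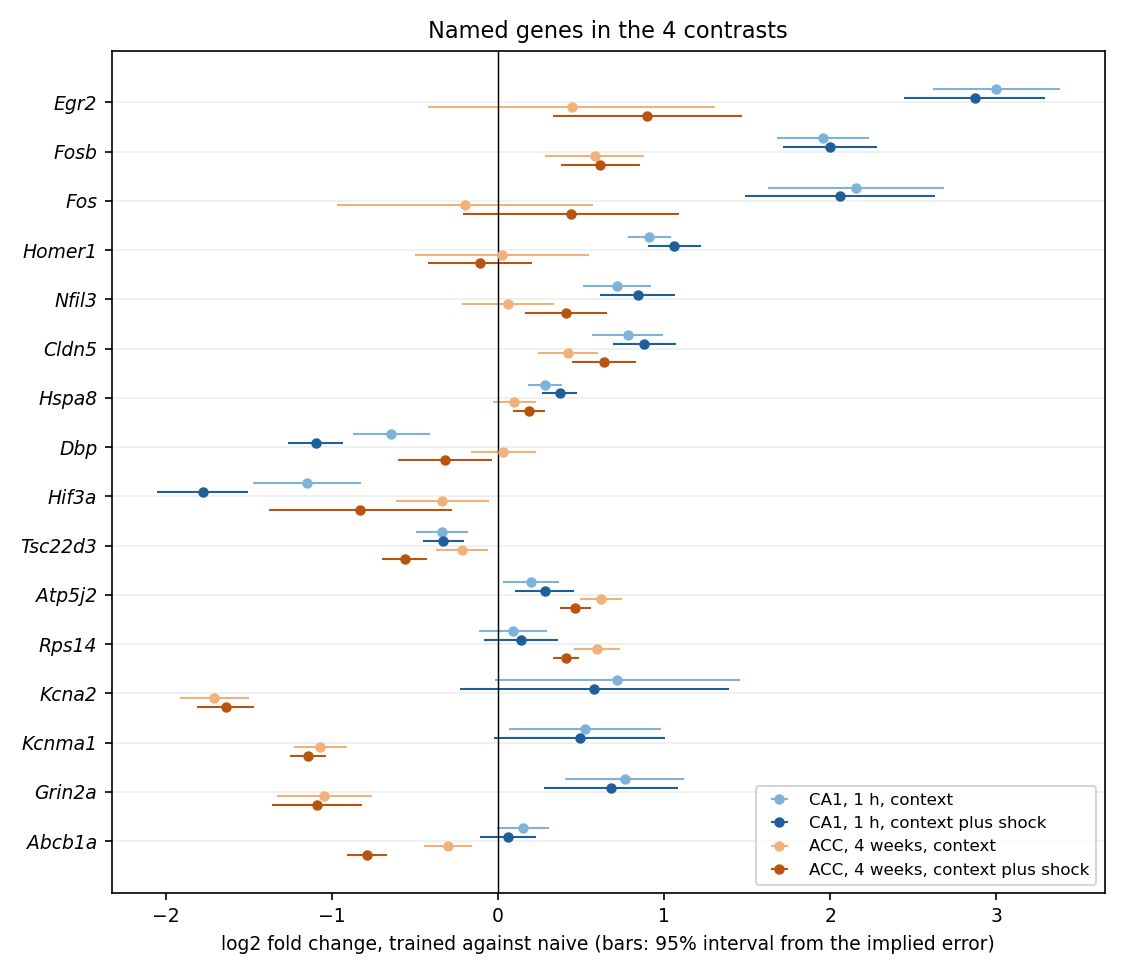
Log2 fold change (x axis, trained against naive) of 16 named genes (y axis) in the 4 contrasts. Points are the authors' deposited values and bars are 95% intervals from the implied errors. Egr2 stands at 3.00 and 2.87 in CA1, and Kcna2 at -1.71 and -1.64 in ACC.

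What the shock added to the context was asked by setting the 2 contrasts of a region against each other. At an unadjusted p under 0.05, 152 of 15034 genes differed in CA1, fewer than that threshold gives by chance alone, and 1824 of 15243 in ACC. After adjustment 1 gene passed in CA1, Ppp1r3c, which targets a phosphatase to glycogen. Ppp1r3c rose by a log2 of 0.25 after context and 0.68 after shock in the authors' deposited tables. Its difference was 0.43 (error at most 0.0908, adjusted p = 0.0295). With the length and GC trend removed its adjusted p was 0.195. Dbp, at -0.64 after context and -1.10 after shock in the authors' deposited tables, differed by -0.46 and did not pass (adjusted p = 1.00, and 0.0689 with the shared naive mice taken out of the error). In ACC 243 of 15243 genes differed, 198 higher and 45 lower after shock. In the authors' deposited tables Robo3, an axon guidance receptor, had -0.64 after context and 0.44 after shock, and Lrrc45, a centrosomal protein gene, -0.11 and 0.79. Slco1a4 differed by -0.62 (adjusted p = 4.03e-05). The differences followed GC content across genes (rho -0.46 in CA1 and 0.58 in ACC), and in ACC 113 genes passed with the trend removed. The test used errors that ignore the shared naive mice and are therefore too large; with the shared part taken out 2 genes passed in CA1 and 1879 in ACC. Of the 1879, 928 were higher and 951 lower after shock, so the lean towards higher values among the 243 was not seen there.

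The fold changes of the 2 contrasts correlated across genes at 0.81 in CA1 and 0.70 in ACC, against 0.47 and 0.49 in simulations of unchanged groups that share their naive mice. The covariance was 0.0406 in CA1 and 0.0416 in ACC, against 0.0112 and 0.00881 simulated. The simulated noise was independent between genes. Shifts of the naive libraries over many genes, such as a length or GC trend, are therefore not in the simulated values. In CA1 314 genes rose in both contrasts and 210 fell in both, where independent lists would share 22.3 and 14.8. In ACC 1018 rose and 1306 fell in both, where independent lists would share 285.8 and 344.2. Opposite calls numbered 0 in CA1 and 17 in ACC. The 2 contrasts of a region use the same naive mice, so the numbers for independent lists are not those for groups without a shared change, and the part of the overlap that comes from the naive mice could not be split here.

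**Figure D3:**
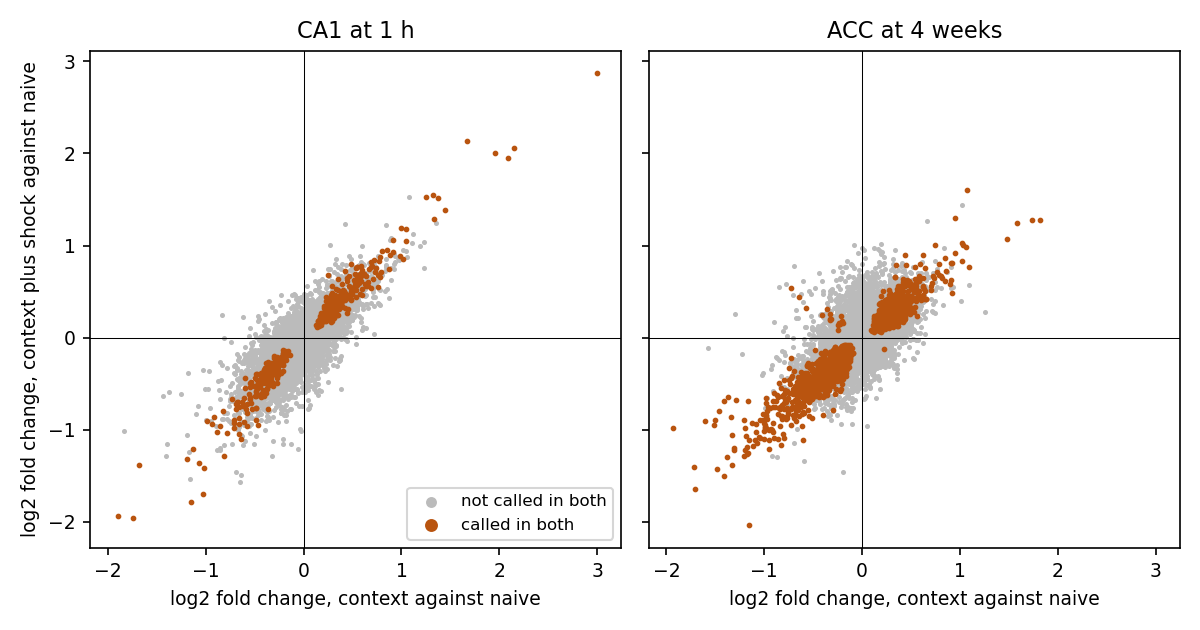
Log2 fold change after context (x axis) and after context plus shock (y axis), both against naive mice, for each gene in CA1 at 1 h (left) and ACC at 4 weeks (right). Coloured points passed in both contrasts. The points lie along the diagonal with correlations of 0.81 and 0.70 across genes. Simulated unchanged groups that share naive mice, with noise independent between genes, gave 0.47 and 0.49.

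Between the regions, which differ in time as well, fold changes correlated across genes at -0.07 after context and -0.14 after shock. After context 39 genes rose in both CA1 and ACC, where 65.5 would be shared by chance, and 69 fell in both, against 53.6 (Fisher's exact test, one-sided, p = 1.00 and 0.0168). Genes that rose in CA1 and fell in ACC numbered 170, against 71.6 by chance (Fisher's exact test, p = 2.32e-28), and those that fell in CA1 and rose in ACC 18, against 49.1 (p = 1.00). The test looks only for an excess over chance. The 39 and 18 genes were fewer than the 65.5 and 49.1 expected, and such a deficit was not tested. After shock 98 rose and 102 fell in both, against 97.1 and 95.1, and 152 rose in CA1 and fell in ACC, against 107.7 (Fisher's exact test, p = 1.33e-06). Those that fell in CA1 and rose in ACC after shock numbered 112, against 85.7 (Fisher's exact test, p = 0.00107). Fold changes after context rose with transcript length in CA1 (Spearman rho 0.17 across genes, which are not independent replicates) and fell with it in ACC (rho -0.61). With GC content they rose in both regions (rho 0.34 in CA1 and 0.21 in ACC). Opposite length trends can add opposite calls. With the trend removed, as given next, genes higher in CA1 and lower in ACC still outnumbered those expected by chance after both trainings. The fitted trend is therefore not the whole source of that excess, and how much it added was not tested. With the length and GC trend removed in both regions, chosen after seeing the data, the correlations were -0.0225 and -0.12. After context 14 genes then rose in both and 24 fell in both, against 11.9 and 12.9 (Fisher's exact test, one-sided, p = 0.303 and 0.00259). Those that rose in CA1 and fell in ACC numbered 42, against 14.8, and the reverse 13, against 10.4 (Fisher's exact test, p = 8.27e-10 and 0.242). After shock 58 rose in both and 66 fell in both, against 46.1 and 53.4 (Fisher's exact test, p = 0.0382 and 0.0385). Those that rose in CA1 and fell in ACC numbered 78, against 48.2, and the reverse 110, against 51.0 (Fisher's exact test, p = 9.38e-06 and 1.39e-15). Each class after shock then exceeded the number expected by chance. The test takes every gene as equally likely to be called, and genes of the same mean level were not compared. The excess is therefore not evidence of shared or opposite regulation. Kcnq3 in the authors' deposited tables had 0.78 and 0.66 in CA1 and -1.06 and -1.08 in ACC, Grin2a 0.76 and 0.68 against -1.05 and -1.09, and Tnr, a matrix protein of perineuronal nets, 0.62 and 0.69 against -0.98 and -0.84.

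Exon usage was compared per exonic bin, whose fold change is taken relative to the rest of the gene. In CA1 few bins passed: 101 bins in 85 genes after context and 122 bins in 107 genes after shock. Homer1 led both, with 1 bin higher and 2 lower each time. In the authors' deposited tables its bin E014 had a log2 fold change of 0.62 after context (adjusted p = 1.33e-15), and its bin E025 -0.25 after shock (adjusted p = 1.12e-24). Bin E044 of the synaptic gene Dlgap1 was higher, with 0.58 after context and 0.72 after shock in the authors' deposited tables. Rasgrf1, an exchange factor of Ras, had a bin at 0.25 and the kinase gene Camk4 a bin at -0.03 after shock in the authors' deposited table. Bin E001 of Sphk2 had -0.27 and -0.46 in the authors' deposited tables; Sphk2 overlaps Dbp, and the strand used in counting is not stated. Of the genes with a changed bin in the gene tables, 16 of 76 after context (21.1%) and 16 of 94 after shock (17.0%) were called as genes, against 8.03% and 6.05% of all genes listed. Genes of the same mean level, a comparison added after seeing the data, would give 8.75 and 6.59 such genes.

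In ACC 3747 bins in 2333 genes passed after context and 2106 bins in 1420 genes after shock, 64.2% and 67.9% of them higher. The synaptic vesicle gene Sv2b, the active zone gene Bsn and the kinase gene Prkcb each had 1 bin higher and 4, 5 and 16 lower after context. The higher bin of Prkcb had a log2 fold change of 0.35 in the authors' deposited table (adjusted p = 5.01e-77). After shock Pclo, another active zone gene, had 1 bin higher and 4 lower. Of the genes with a changed bin 730 of 2194 after context (33.3%) and 910 of 1322 after shock (68.8%) were called as genes, against 19.6% and 41.6% of all genes listed and 654.6 and 836.4 for genes of the same mean level. The bin with the lowest number, E001, was higher in 702 of 706 cases after context and 417 of 426 after shock among genes on the minus strand, and in 0 of 35 and 0 of 5 on the plus strand. In CA1 it was lower in 17 of 17 and 21 of 22 cases on the minus strand, and higher in 1 of 1 case on the plus strand in each contrast. Bins called in both ACC tables numbered 1751, of which 1746 had the same sign; the tables share their naive mice, which favours the same sign, and by how much was not tested.

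**Figure D4:**
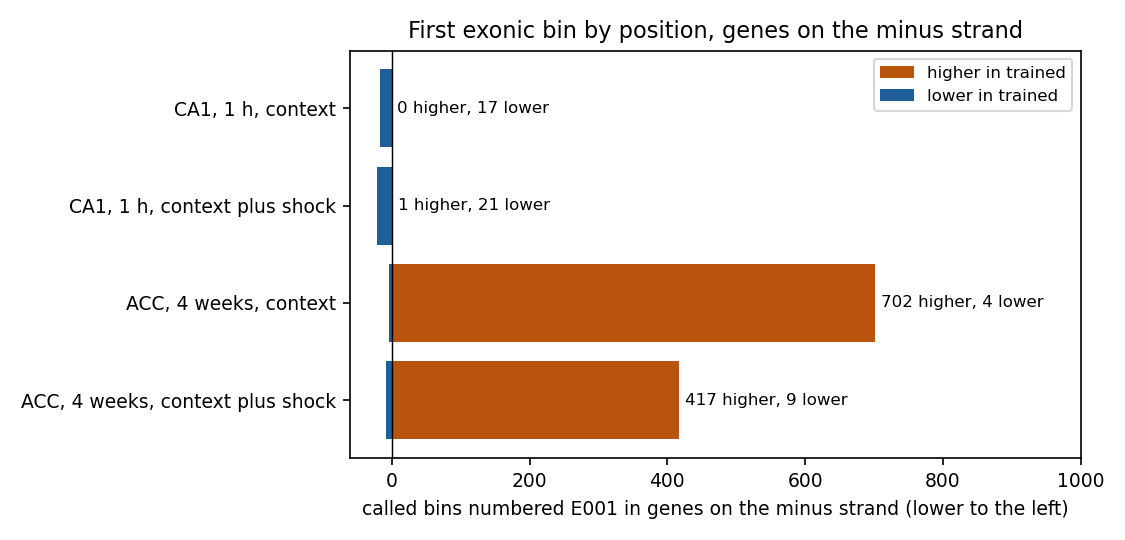
Number of called bins numbered E001 in genes on the minus strand (x axis, lower bins to the left of 0) in each contrast (y axis). In ACC 702 and 417 were higher and 4 and 9 lower; in CA1 0 and 1 were higher and 17 and 21 lower.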

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

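The tests of the difference between the regions were chosen after results were seen. Of the tests of explanations, those of the length and GC trend as the whole cause of the list changes and of Nnt bins were written before their result was seen; all others were chosen after it.

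The difference between the regions flagged these results: the same training was followed by different changes in ACC at 4 weeks and CA1 at 1 h, by a test of the difference. Region and time differ together, and which of them matters was not tested. After context 2141 genes differed and after context plus shock 3731. The ACC minus CA1 difference in median log2 fold change after context was -0.50 for immediate early genes, -0.24 for delayed activity genes and -0.25 for endothelial and pericyte markers. It was 0.28 for ribosomal protein genes, 0.25 for oxidative phosphorylation genes and 0.20 for microglial markers. For oligodendrocyte precursor markers it was -0.0499, for glutamate receptors -0.0718, for synaptic adhesion genes -0.22, for potassium channels -0.23, for histone methylation genes -0.16 and for extracellular matrix genes -0.093. After context plus shock it was -0.28 for immediate early genes, -0.30 for delayed activity genes, -0.54 for endothelial markers, 0.19 for ribosomal protein genes and 0.15 for oxidative phosphorylation genes. For GABA receptors it was -0.31, for synaptic adhesion genes -0.21 and for potassium channels -0.23. With the length and GC trend removed in both regions 867 and 2075 genes differed. After context the difference then turned to 0.055 for glutamate receptors and 0.0414 for extracellular matrix genes and shrank to -0.0436 for histone methylation genes, -0.0392 for synaptic adhesion genes and 0.0929 for microglial markers (adjusted p = 0.919, 0.675, 0.675, 0.252 and 0.326). For oligodendrocyte precursor markers it was -0.048 and not past the threshold (adjusted p = 0.287). It was 0.0457 for ribosomal protein and 0.0459 for oxidative phosphorylation genes (adjusted p = 0.0381 each) and -0.0674 for potassium channels (adjusted p = 0.00175). After context plus shock it was 0.0476 for ribosomal protein and 0.0126 for oxidative phosphorylation genes, no longer past the threshold (adjusted p = 0.252 and 0.818). It was -0.16 for GABA receptors, -0.0756 for synaptic adhesion genes and -0.13 for potassium channels (adjusted p = 0.00635, 0.0136 and 9.26e-06). Glucocorticoid-responsive and cholesterol synthesis genes gained a call after context plus shock, with differences of -0.19 and -0.0633. Their cameraPR adjusted p went from 0.129 to 0.00635 and from 0.137 to 0.0381. The differences of immediate early, delayed activity and endothelial genes stayed past the threshold after both trainings (adjusted p at most 0.00014).

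The first pattern is that list and exon changes follow transcript length and position. With the length and GC trend removed, 4 of 4 calls of the oxidative phosphorylation and ribosomal lists in ACC stayed. So did 4 of 5 of the potassium channel, synaptic adhesion and GABA receptor lists in ACC, and 6 of 6 of the immediate early, delayed activity and endothelial lists in CA1. The fit leaves out the length of the 3' untranslated region, which fold changes in ACC also follow (Spearman rho -0.40 after context and -0.51 after shock). Calls that stayed in ACC therefore do not exclude such a trend as the whole cause, while those in CA1 argue against it. The medians of these sets moved from 0.23 to 0.0391, from -0.18 to -0.0945 and from 0.29 to 0.26. The synaptic adhesion call in ACC after context ended as its median went from -0.14 to -0.0399. In ACC after shock the synaptic adhesion median went from -0.18 to -0.0572 and the GABA receptor median from -0.26 to -0.0945. Most of the size of the oxidative phosphorylation, ribosomal, synaptic adhesion and GABA receptor changes in ACC thus goes with the trend. For the potassium channel changes it is a part. More reads at the 3' ends of transcripts in trained than in naive ACC, as lower RNA quality or another library batch could give, fits. Bin E001 of genes on the minus strand, their 3' end if bins are numbered by position, was higher in 702 of 706 cases after context and 417 of 426 after shock. Both contrasts use the same naive mice, so fewer 3' reads in the naive libraries alone could give both counts, which are not independent. In CA1 the same shift is argued against (higher in 0 of 17 and 1 of 22). The opposite one, away from the 3' ends, stays open, untested. The other 17 and 21 bins were lower there, and the 1 called bin on the plus strand was higher in each contrast. An effect of training on ACC transcripts stays open, untested.

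The second pattern is Wdfy1, Nnt and Cd59a, higher in ACC at 4 weeks. With the length and GC trend removed, 3 of the 3 genes stayed called in both ACC contrasts. They were chosen for a small p after context, which made this outcome likely, so no conclusion is drawn from it. In ACC after context log2 fold changes went from 1.74 to 1.78 for Wdfy1, 0.91 to 0.89 for Nnt and 1.48 to 1.37 for Cd59a. The fitted trend thus holds little of the size of these changes there. An Nnt allele difference between the mice cannot be told apart from an effect of training: 0 Nnt bins were listed after context, but the tables list only bins under an adjusted p of 0.1, so the bound written for this test was wrong to take an absent bin as evidence. Mice of different genotype within the ACC shock group fit, with a median ratio of implied errors, shock over context, of 2.20 where the 95th percentile of genes is 1.00, though the wording of this test was changed after values were seen and genes chosen for a small p after context tend to have a small error there. An effect of training stays open, untested.

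The third pattern is the change of clock genes in CA1 at 1 h and ACC at 4 weeks. Whether induction of activity-regulated clock genes alone is the cause could not be decided. In CA1 after shock 7 E-box and D-box driven genes were called lower, but Nfil3, which binds the same sites as Dbp, rose by a log2 of 0.84. Its induction might itself lower such genes, so their fall excludes nothing. The length and GC trend is argued against in CA1 after shock, where the list stayed called lower with it removed (cameraPR adjusted p = 9.02e-07). Sampling at another time of day cannot be told apart from training. After the values were seen, 9 measured E-box and D-box driven genes and 4 antiphase genes were each given a side. Of the called ones, 7 of 7 in CA1 after context moved to the side that a shift in phase gives. In CA1 after shock 9 of 9 did so, and in ACC after shock 9 of 10. The 1 exception, Clock, misses the bound of all genes. In ACC after context, which shares its naive mice with ACC after shock, 0 of 1 called genes (Clock, lower) lay on that side. Other called clock genes were given no side, among them Bhlhe40, higher in CA1 after context (log2 0.40). Over the whole list 4 genes were higher and 7 lower in CA1 after context, and 4 and 9 in CA1 after shock. A bound of 75% was tried for this test after the values were seen and was dropped. It would have been met in both CA1 contrasts and in ACC after shock, but not in ACC after context. The labels state no times of day.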

How the results depend on the processing

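Settings with the length and GC trend removed were chosen after seeing the data; the others were chosen before the files were opened. No paired analysis was possible because the tables give 1 value per comparison and none per library. For the same reason count models, other normalisations, filters on counts per library, pseudocounts, leaving out libraries, other splits of the samples and lists with an estimated correlation were not run, and the limit set by depth is unknown. Lists called in neither setting were not compared. The number of lists that differ between the regions after context fell by more than 1.5 times with the trend removed, as given above. Apart from this and the moves below, every count of calls of genes, exonic bins, lists and overlaps that was compared stayed within 1.5 times. The cause of the moves was not tested, except that stricter thresholds keep fewer genes by construction.

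At an adjusted p under 0.01, genes numbered 519 (CA1 context), 435 (CA1 shock) and 1809 (ACC context), exonic bins 38, 62 and (ACC shock) 1392, overlaps of context and shock 231 (CA1) and 1413 (ACC), and genes also changed in exons 7 (CA1 context). At an adjusted p under 0.1, genes numbered 1404 (CA1 shock), the overlap in CA1 816, and genes called in both regions, in the order both higher, both lower, CA1 higher with ACC lower and the reverse, 78, 128, 291 and 45 after context and 157, 175, 255 and 190 after shock. With an absolute log2 of at least 0.25, genes numbered 730 (CA1 context), 1700 and 3147 (ACC), and bins 32, 39, 903 and 389. With the trend removed, genes numbered 560 (CA1 context), 1356 and 3668 (ACC), lists 6 (ACC context), genes called in both regions, in the order above, 14, 24, 42 and 13 after context and 58, 66, 78 and 110 after shock, and genes that differ between shock and context 0 (CA1) and 113 (ACC); with the shared naive mice out of the error the last were 2 and 1879. Genes that differ between the regions went from 2141 to 867 after context and from 3731 to 2075 after shock with the trend removed, and of 11 lists that differ between shock and context in CA1 7 stayed. Of the genes called in CA1 after shock 485 were higher and 430 lower, 389 and 432 with the trend removed and 372 and 377 with an absolute log2 of at least 0.25. Of the calls of genes picked by the naming rule, without the genes not reported here, 254 stayed with the trend removed, 86 were lost and 10 reversed: Bsn -0.0251 (CA1 context), Cck -0.0187 (ACC context), and in ACC after shock Spred1 0.0347, Cck -0.10, C1qc -0.0461, Sema5a 0.0194, Foxp1 0.00479, Mbd3 -0.0331, Tet2 0.00126 and Pmvk -0.0316. Of list calls 24 held at a correlation of 0.05, 28 with ranks, 30 with a mean of at least 50 and 25 with the trend removed; lists not called as reported gained a call in 0, 2, 1 and 3 cases, in the same order. The 6 lists of ACC after context are 5 of the 10 called and the glucocorticoid list, which was gained.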

Other observations

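The tests of lists between shock and context in this part were chosen after seeing the data. In CA1 the cholesterol synthesis list was higher after shock than after context (adjusted p = 1.90e-07, medians 0.08 and 0.0295), as were delayed activity genes (adjusted p = 5.50e-05), oxidative phosphorylation genes (adjusted p = 4.19e-06), chaperones (adjusted p = 0.00503) and markers of CA1 pyramidal neurons (adjusted p = 0.0132). Clock genes (adjusted p = 0.000496) and astrocyte markers (adjusted p = 0.00825) were lower. In all 11 of 31 lists were called in CA1, and 7 of them stayed with the length and GC trend removed.

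In ACC the endothelial and pericyte list was lower after shock than after context, with medians of -0.27 and 0.0538 (adjusted p = 9.80e-11). Markers of blood cells (adjusted p = 0.0132) and microglia (adjusted p = 0.0112), GABA receptors (adjusted p = 0.000297), glucocorticoid-responsive genes (adjusted p = 0.000786) and astrocyte markers (adjusted p = 0.0252) were lower too, and histone methylation genes were higher (adjusted p = 0.00944). Of 31 lists 9 were called, and 7 stayed with the trend removed. The test ignores the shared naive mice, and the labels give no age at sacrifice for the naive mice of ACC beside those taken 4 weeks after training.

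Exonic bins called in both CA1 tables numbered 49, of which 48 had the same sign; the tables share their naive mice, which favours the same sign, and by how much was not tested. Ide and Fgfbp3, chosen after their values were seen, had ratios of implied errors, shock over context in ACC, of 3.20 and 1.95.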
